A study of Oryza sativa with 4 samples.

How the data were processed

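Each of the 4 arrays carried the RNA of 1 antisense OsDDM1 plant and 1 wild-type plant, labelled with Cy5 and Cy3. Per the labels, plants were grown in a greenhouse for about 2 months, young leaves were taken before the boot stage, the antisense fragment was 2 kb long and driven by the 35S promoter, and the antisense plants were siblings of 1 line descended from a plant regenerated from callus. Each pair of extracts was hybridised on 2 arrays with the dyes exchanged, so the 2 arrays of a pair were averaged and counted as 1 replicate (n = 2 pairs). All arrays were on 1 slide.

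Per the file headers, the scanner files came from Agilent Feature Extraction 9.1.3.1 and hold mean spot intensity and median local background intensity in each channel, without normalization. The deposited processed intensity values were background-subtracted, detrended and dye-normalized by that software, per the file headers. The deposited log10 ratio is red over green from those processed signals, and the deposited p-value per spot covers error within the array, per the file headers. The deposited series table of log10 ratios equalled the scanner log10 ratios within 0.0050 for 100% of spots once turned to antisense over wild type. Its 4 columns had a median of 0, and its scale, centring and direction were settled by that match. Genome build and gene model version are not given in the sources used here, so no coordinates were used and neighbours were taken from the order of locus names.

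Of 45151 spots, 42105 carry rice locus names, 1020 microRNA loci, 590 design controls and 1417 scanner controls. Between 69.6% and 74.1% of spots were well above background per channel, 0 were saturated, and between 59 and 137 per array were outliers and left out. Intensities were corrected with normexp (offset 50) and normalized by loess within arrays in limma 3.58.1 (R 4.3.3), control spots having no weight, and each log2 ratio was turned to antisense over wild type. Levels per plant are separate-channel values after loess and Aquantile, averaged over 2 arrays. A gene was tested if well above background in the antisense channel on 4 arrays or in the wild-type channel on 4 arrays. The probe with the highest mean signal stood for a gene, and of 6077 genes with several such probes 0 had probes that differed by over 1 in both directions. Probes of a gene could still differ in the size of the ratio. Gene names are those of the array file, since 0 tested genes matched the RefSeq table by locus name, and the names OsDDM1a and OsDDM1b were set by locus.

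Where a gene was not well above background on any array of one genotype, its fold is a lower bound ("at least"): the mean of the brighter genotype against, per array, the higher of the lowest signal well above background and the gene's own signal. Where the dimmer genotype was well above background on some arrays but not all, the fold depends on the background correction. Genes were tested with limma's lmFit and eBayes on the log2 ratios against 0 (two-sided, 1 residual degree of freedom), adjusted by Benjamini-Hochberg, at an adjusted p under 0.05. Gene lists written from locus names and description words were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. Neighbouring genes were counted within 5 tested loci and set against 10000 permutations. Probe sequences of 60 bases were compared with blastn 2.17.0, and probes with at least 90% identity over at least 45 bases were taken to resemble one another. Only probes on the array were compared, so sequence shared with loci that have no probe was not seen.

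The tests, the fold threshold of 2, the lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule names the 10 higher and 10 lower genes with the smallest p among those at least 2-fold in one direction on all 4 arrays with a product named, since none passed the adjusted p. It also names the target genes, up to 4 genes per list with the smallest p, and the genes of the methylation, flowering-time and clock lists. Words that put genes into a list by chance letters were removed after the descriptions and some single-gene values had been read and before any list result was computed. The set of genes at least 2-fold in both pairs took the place of called genes in the position test, since none were called. Fisher's exact tests of list members in that set, the reordering of directions among genes at least 2-fold different in both pairs, the comparison of probe sequences, the fits without the plant labelled wild type 1, and the genes said to be chosen after their values were seen came after the data had been examined.

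The steps were tested on simulated data. The genes of each pair were reordered independently, 200 genes were given known changes, and the spread of the real ratios was kept. With 50 genes per size, 0 were called at log2 changes of 1, 2, 4 or 6, and the rule of 2-fold in both pairs found 20%, 90%, 98% and 100% of them, along with 127 of 20156 unchanged genes (0.63%). The reordering also removed variability that a gene shares between the pairs. In the real data genes in opposite directions outnumbered those of independent lists, so 0.63% may be too low for them. Alternatives covered background correction, normalization, the filter on dim probes, the probe rule, single dye orientations, fits with the pairs as a block or without pairing, the empirical Bayes settings, and leaving out each pair.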

Results

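Gene expression was measured in young leaves of rice (Oryza sativa, cultivar Nipponbare) carrying an antisense construct against OsDDM1 and in wild-type leaves. DDM1 is a chromatin remodelling ATPase known from Arabidopsis for keeping DNA methylated and transposons silent. Antisense plants 1 and 2 were siblings of 1 transgenic line, and each was set against 1 wild-type plant on 2 two-colour arrays with the dyes exchanged, which gives 4 arrays and 2 plant pairs. Median spot signals lay between 252 and 396 in Cy3 and between 459 and 745 in Cy5, over local backgrounds of 58 to 63, and the number of arrays limits the precision. The expression of 20356 genes was tested. The design asks which genes differ between antisense OsDDM1 and wild-type leaves.

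The target was examined first. OsDDM1b (Os03g0722400, a SNF2-related protein and the paralog of the gene the construct was made from) was 3.60-fold lower in antisense plant 2 than in wild-type plant 2, at a log2 ratio of -1.85. In pair 1 its log2 ratio was -0.01, so the mean over the pairs was -0.93 ± 1.30 (SD, n = 2). The level on the log2 scale was 8.27 and 8.45 in antisense plants 1 and 2, 8.28 in the plant labelled wild type 1, and 10.29 in wild-type plant 2. The level of this 1 probe of a paralog thus goes against the label of the first wild-type plant, which is called the plant labelled wild type 1 throughout. At the 47 genes at least 8-fold higher in pair 2, that plant was near wild-type plant 2, at a median log2 ratio of -0.0157. The direction of every pair 1 ratio rests on that label. The probe for OsDDM1a itself (Os09g0442700), whose clone gave the antisense fragment, was not well above background in either channel of any array.

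Genes with no product named were left out of the ranking by p-value. Among the named genes higher in the antisense plants, those with the smallest p-values included transposon genes, a receptor kinase, a jasmonate signalling gene and PR-1. A BURP domain gene (Os10g0409400) was at least 48.9-fold higher, since its wild-type signal was not well above background on any array, and its log2 ratio was 5.63 ± 0.55 (SD, n = 2 pairs). A ZIM domain gene (Os07g0153000), a class known for repressing jasmonate responses, was 104-fold and 50.4-fold higher in pairs 1 and 2, with a probe that resembles probes of 2 other loci. A kinase related to BAK1 (Os11g0514400), a co-receptor in brassinosteroid and immune signalling, was at least 15.3-fold higher and a homeodomain-like gene (Os01g0549300) at least 9.61-fold. PR-1 (Os01g0382000), a classical pathogenesis-related gene, was 9.64-fold higher in pair 1 and 21.1-fold in pair 2. Being at least 2-fold higher on all 4 arrays was part of the rule that chose these genes.

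Among genes with a product named that were lower in the antisense plants, those with the smallest p-values included a light harvesting gene, PAL2 and disease resistance genes. The chlorophyll a-b binding protein CAB1 (Os09g0346500) was 4.82-fold and 5.09-fold lower in pairs 1 and 2, and PAL2 (Os04g0518400), phenylalanine ammonia-lyase at the entry to phenylpropanoid synthesis, was 6.31-fold and 3.32-fold lower, while another phenylalanine ammonia-lyase gene (Os12g0520200) was 2.18-fold and 3.22-fold higher. An RNase S-like gene (Os09g0538000) stood at a log2 ratio of -2.35 ± 0.30, and an aspartic peptidase (Os06g0118700) at -2.54 ± 0.93. The 12 probes of the RNase S-like gene had mean log2 ratios from -2.37 to -0.82, and the 6 of CAB1 from -2.31 to -1.33. Genes for an AMP-dependent synthetase (Os07g0280200, 3.77-fold), a raffinose synthase (Os07g0209100, 4.17-fold), a P-glycoprotein homologue (Os01g0723800, 3.12-fold) and a benzoyl transferase (Os10g0503300, 3.07-fold) were lower as well, as was the NBS-LRR gene Os11g0226800 (at least 5.14-fold). The NBS-LRR gene Os11g0225300 had a log2 ratio of -2.41 ± 0.16, and of -5.03 with processed signals, its antisense signal being well above background on 1 of 4 arrays.

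None of these genes passed the test over all genes. With limma and Benjamini-Hochberg adjustment 0 genes were called higher and 0 lower, and the smallest adjusted p was 0.54. At an unadjusted p under 0.05 there were 443 higher and 129 lower genes, 572 in all, where evenly spread p-values would give 1018. The ratios had an SD over genes of 1.10 in pair 1 and 0.50 in pair 2, so such an even spread is not assured. The fit of 4 arrays with a replicate block called 0 genes (991 at an unadjusted p under 0.05), as did the fit without pairing (756) and the fit with an intensity trend (697). The scanner software's own p, which covers technical error within an array, was under 0.01 on all 4 arrays for 704 genes higher and 274 lower. In simulated data with the spread of these pairs, limma called 0 of 200 changed genes, 50 of them with a log2 change of 6 in both pairs.

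Counted by size alone, 284 genes were at least 2-fold higher in both pairs and 70 were at least 2-fold lower. In opposite directions, 142 genes were higher in pair 1 and lower in pair 2, and 84 the other way. Lists of independent genes of these lengths would share 93.3, 25.6, 57.3 and 41.7 genes, so the overlap exceeded them in opposite directions too. With the directions of pair 2 reordered among these 580 genes, 284 stood against a mean of 270 and a highest count of 287 (10000 reorderings, one-sided permutation p = 0.0054). Without probes that resemble another locus, 200 stood against a mean of 200 (permutation p = 0.51). At 4-fold, 77 genes were higher in both pairs against at most 76 (permutation p = 1e-04, the smallest they can give), and 62 against at most 61 without such probes. These reorderings keep the number of genes in each direction, so a rise shared by the pairs is partly counted as chance. Of the 284 higher genes, 31 were at least 8-fold higher in both pairs and 17 at least 16-fold, against 1 of the 70 lower genes at 8-fold. For 60 of the 284, the wild-type channel was not well above background on any array. The file named no product for 172 of the 284 (60.6%), 22 of the 70 (31.4%) and 37.0% of all tested genes. Probes of 84 of the 284 (29.6%) and 17.1% of the 70 resembled a probe of another locus, against 4.15% of all tested genes. Joined by such resemblance, the 284 genes formed 219 families, the largest of 32 genes, so they are not all separate signals. The probe that resembled most others made up, with them, 30 loci with no product named, all 30 higher in both pairs, with medians of 3.61-fold and 2.74-fold in pairs 1 and 2.

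**Figure D1:**
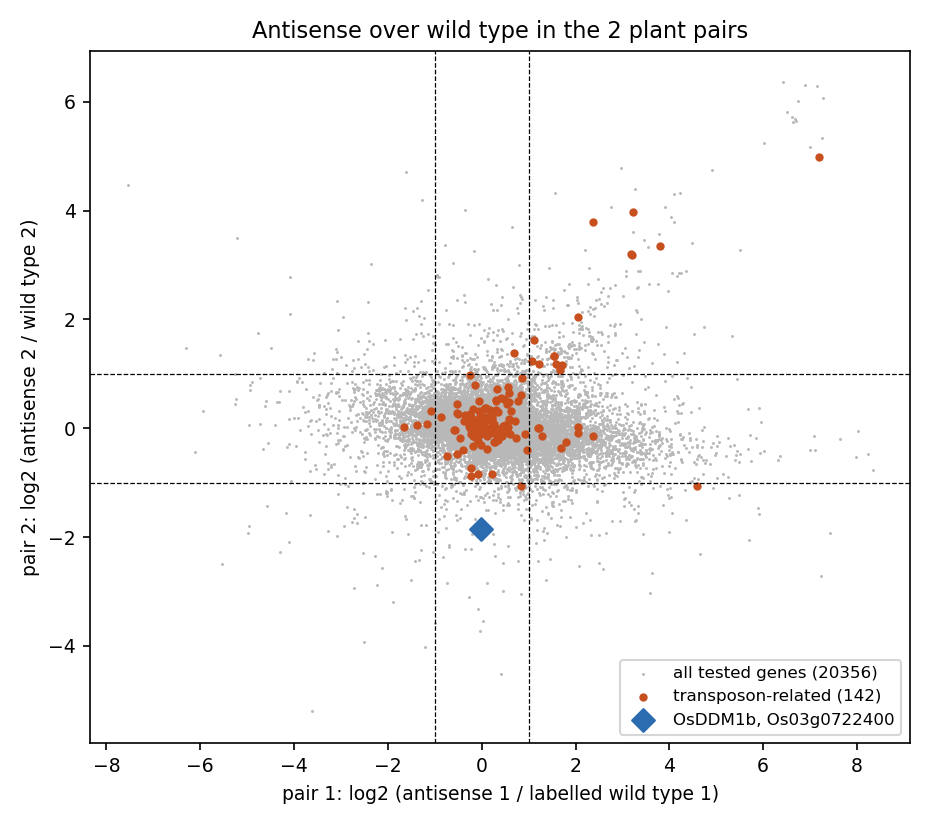
Each point is 1 gene, with its log2 ratio of antisense over wild type in pair 1 on the horizontal axis and in pair 2 on the vertical axis, each the mean of 2 dye-swapped arrays. Dashed lines mark 2-fold, and of the 142 transposon-related genes in orange 15 lie above both lines in the upper right and 0 below both in the lower left.

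Retrotransposon genes had the smallest p of the lists when members 2-fold different in both pairs were counted. Of 50 tested genes described as retrotransposon-like, 12 (24%) were at least 2-fold higher in both pairs and 0 were lower in both, against 1.40% of all tested genes (two-sided Fisher's exact test, adjusted p = 2.74e-10 over 84 tests, with genes that are not independent replicates). The filter lets silent genes in only when they are bright in one genotype, and without it the count was 12 of 117 (adjusted p = 1.18e-07), while 1 of 33 was left with signal above background required in both channels (adjusted p = 1). For 8 of the 12 the wild-type signal was not well above background on any array, so that their folds are lower bounds. An integrase gene (Os11g0224300) was at least 10.8-fold higher, and gag genes were at least 8.82-fold (Os05g0374700), 9.18-fold (Os12g0428300) and 12.1-fold higher (Os06g0493000), the last 2 well above background in wild type on 1 and 2 of 4 arrays. Adjusted over the list alone, 5 members passed, the smallest adjusted p being 0.015, against 0 over all genes. The list median was 0.21 ± 0.17 (SD, n = 2 pairs; camera, adjusted p = 1.19e-04), with adjusted p = 0.90 with an estimated correlation. The median was 0.0314 (adjusted p = 0.033) without the filter on dim probes and 0.05 (adjusted p = 0.86) with both channels required.

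Among 92 DNA-transposon-like genes 3 were at least 2-fold higher in both pairs and 0 lower. All 3 are En/Spm-like: Os07g0431000 was 146-fold and 31.7-fold higher in pairs 1 and 2, Os03g0714800 at least 7.62-fold, and Os11g0686000, whose probe resembles that of another locus, 2.23-fold. The list median was 0.08 (camera, adjusted p = 0.46) and adjusted over the list alone 0 members passed. Both lists joined as 142 transposon-related genes had a median of 0.12 ± 0.09 (SD, n = 2 pairs; adjusted p = 0.017), with adjusted p = 0.90 with an estimated correlation, and 15 members at least 2-fold higher in both pairs (Fisher's exact test, adjusted p = 6.01e-08, and 0.72 for the 3 of 116 left with both channels required). Adjusted over the list alone 5 members passed. Without the filter on dim probes the median was 0.03 (adjusted p = 0.11).

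The lists of DNA methylation genes and of chromatin proteins had medians near 0. None of 16 tested genes for DNA methylation and silencing was 2-fold different in both pairs, and their median was -0.05 ± 0.04 (SD, n = 2 pairs). MET1 (Os07g0182900), the maintenance DNA methyltransferase, had log2 ratios of -0.62 and -0.28 in pairs 1 and 2, and chromomethylase 3 (Os05g0224800) of -0.10 and 0.05. Of 114 chromatin proteins, SNF2P (Os03g0101700) was 15.2-fold and 3.63-fold higher, and 113 were not 2-fold different in both pairs. Histone H3 genes Os12g0415800 and Os12g0415400, near one another on chromosome 12, had log2 ratios of 3.46 ± 0.84 and 2.73 ± 0.84, with wild type well above background on 2 and 1 of 4 arrays. The 41 histone genes had a median of 0.32 ± 0.37 (adjusted p = 0.0044), with adjusted p = 0.90 with an estimated correlation, and 0.62 and 0.09 in pairs 1 and 2.

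Defence genes went both ways. Of 104 pathogenesis-related genes 9 were at least 2-fold higher in both pairs (Fisher's exact test, adjusted p = 4.27e-04) and 3 lower (adjusted p = 0.071). With both channels required 9 of 90 were higher (Fisher's exact test, adjusted p = 4.18e-06, the smallest of the lists with that filter) and 2 lower (adjusted p = 0.39). The list as a whole was not called (median 0.07 ± 0.16, camera, adjusted p = 0.43), with 33 members at least 2-fold higher and 9 lower in pair 1, 13 and 14 in pair 2, and 30 lower in the plant labelled wild type 1 than in wild-type plant 2. Thaumatin-like genes Os03g0663400 and Os03g0663500 were 4.68-fold and 5.60-fold higher, and a Bet v I gene (Os12g0555000) 9.25-fold. The 2 probes of the Bet v I gene had mean log2 ratios of 3.21 and 2.12. Of 205 NB-ARC and disease resistance genes 3 were higher and 5 lower in both pairs (adjusted p = 0.015 for the lower ones, of which 0 were left with both channels required), 4 of the 5 lying among 8 neighbouring tested loci on chromosome 11. WRKY24 (Os01g0826400), WRKY67 (Os01g0584900), WRKY69 (Os08g0386200) and WRKY19 (Os05g0571200), transcription factors of a family known in defence, were 5.26-fold, 2.93-fold, 3.16-fold and 2.52-fold higher, and 1 of the 52 tested WRKY genes was lower in both pairs (4 higher, Fisher's exact test, adjusted p = 0.071, and camera, adjusted p = 0.49). WRKY67 was well above background in wild type on 2 of 4 arrays. Among 29 jasmonate-related genes the lipoxygenases Os12g0559200 and Os12g0560200 had log2 ratios of -3.45 ± 2.16 and -2.87 ± 1.85, while Os07g0153000 alone passed when adjusted over the list alone (adjusted p = 0.0091). So did Os11g0514400 among 62 receptor-like kinases (adjusted p = 0.028). In these 5 lists 0 members passed over all genes.

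**Figure D2:**
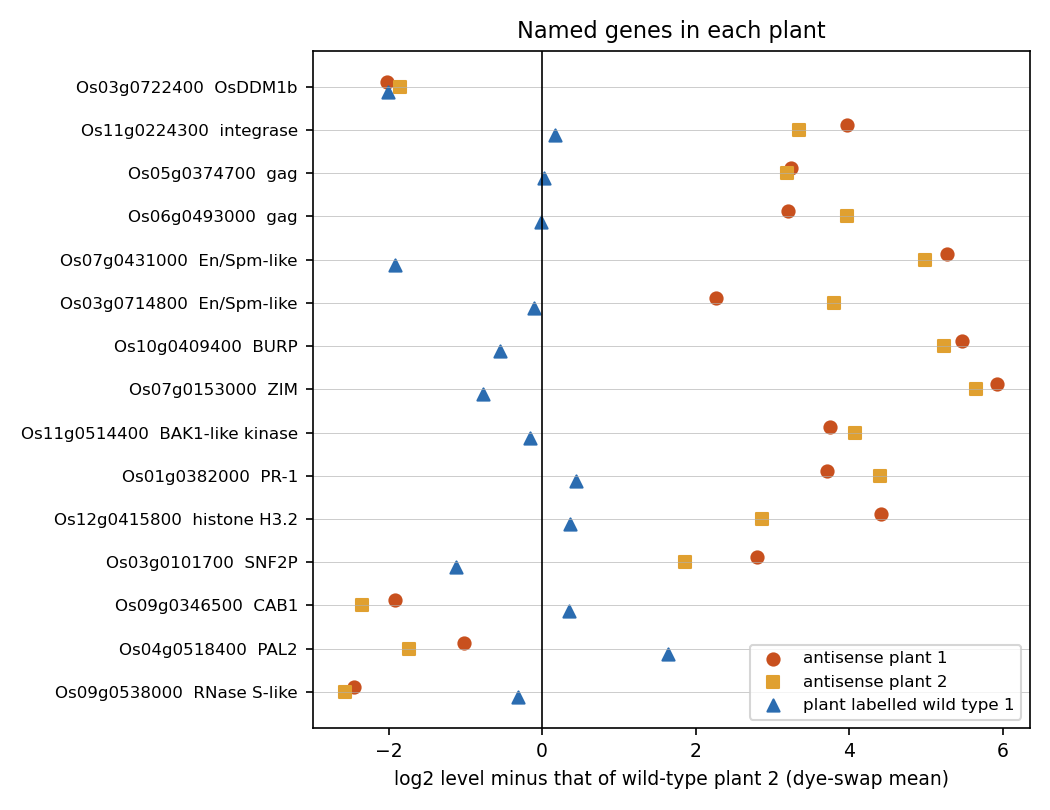
Points give the log2 level of each gene in antisense plants 1 and 2 and in the plant labelled wild type 1, minus its level in wild-type plant 2 (vertical line at 0), as means of 2 arrays. OsDDM1b stands about 2 log2 units below wild-type plant 2 in the other plants, the integrase, gag and En/Spm-like genes stand above it in both antisense plants, and signals not well above background are drawn as measured.

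Photosynthesis and ribosome genes had different medians in pairs 1 and 2, a difference that was not tested. The 65 photosynthesis genes had medians of 2.59 in pair 1 and -0.45 in pair 2 (camera over both, adjusted p = 0.091), and 43 of them were at least 2-fold lower in the plant labelled wild type 1 than in wild-type plant 2. The 46 plastid ribosomal protein genes had medians of 1.68 and 0.10 (adjusted p = 0.0042), with adjusted p = 0.90 with an estimated correlation, and 24 were at least 2-fold lower in the plant labelled wild type 1 than in wild-type plant 2. The 238 cytosolic ribosomal protein genes had medians of -0.69 and 0.30, and a joint median of -0.19 ± 0.71 (adjusted p = 1.19e-04), with adjusted p = 0.90 with an estimated correlation. The joint direction turned without pair 1, to 0.30. CAB1 (Os09g0346500) and the 22 kDa protein of photosystem II (Os04g0690800) were the photosynthesis genes at least 2-fold lower in both pairs.

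Other lists held few genes at least 2-fold different in both pairs. Of 138 cytochrome P450 genes 5 were higher (Fisher's exact test, adjusted p = 0.34) and 1 lower, and of 78 peroxidase and antioxidant genes 2 and 1. Of 8 circadian clock genes (median -0.01 ± 0.45) the response regulator Os09g0532400 was 3.74-fold and 2.48-fold lower, and of 6 tested flowering-time genes (median 0.40 ± 0.41) 0 were 2-fold different in both pairs, with Hd1 (Os06g0275000) at log2 ratios of 0.97 and 0.34. Of 30 iron and metal genes 2 metallothioneins (Os12g0570700 and Os12g0571100) were higher in both pairs, the second 12.3-fold and 2.29-fold with a probe that resembles that of another locus and wild type well above background on 2 of 4 arrays. The list median was 0.20 ± 0.15 (camera, adjusted p = 0.45). Among 5 lists of other tissues the medians in pair 2 were between -0.21 and 0.10, and in pair 1 between -0.15 and 1.74. Of 42 lists tested with camera 5 had an adjusted p under 0.05, 0 of them with an estimated correlation and 0 with fry.

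**Figure D3:**
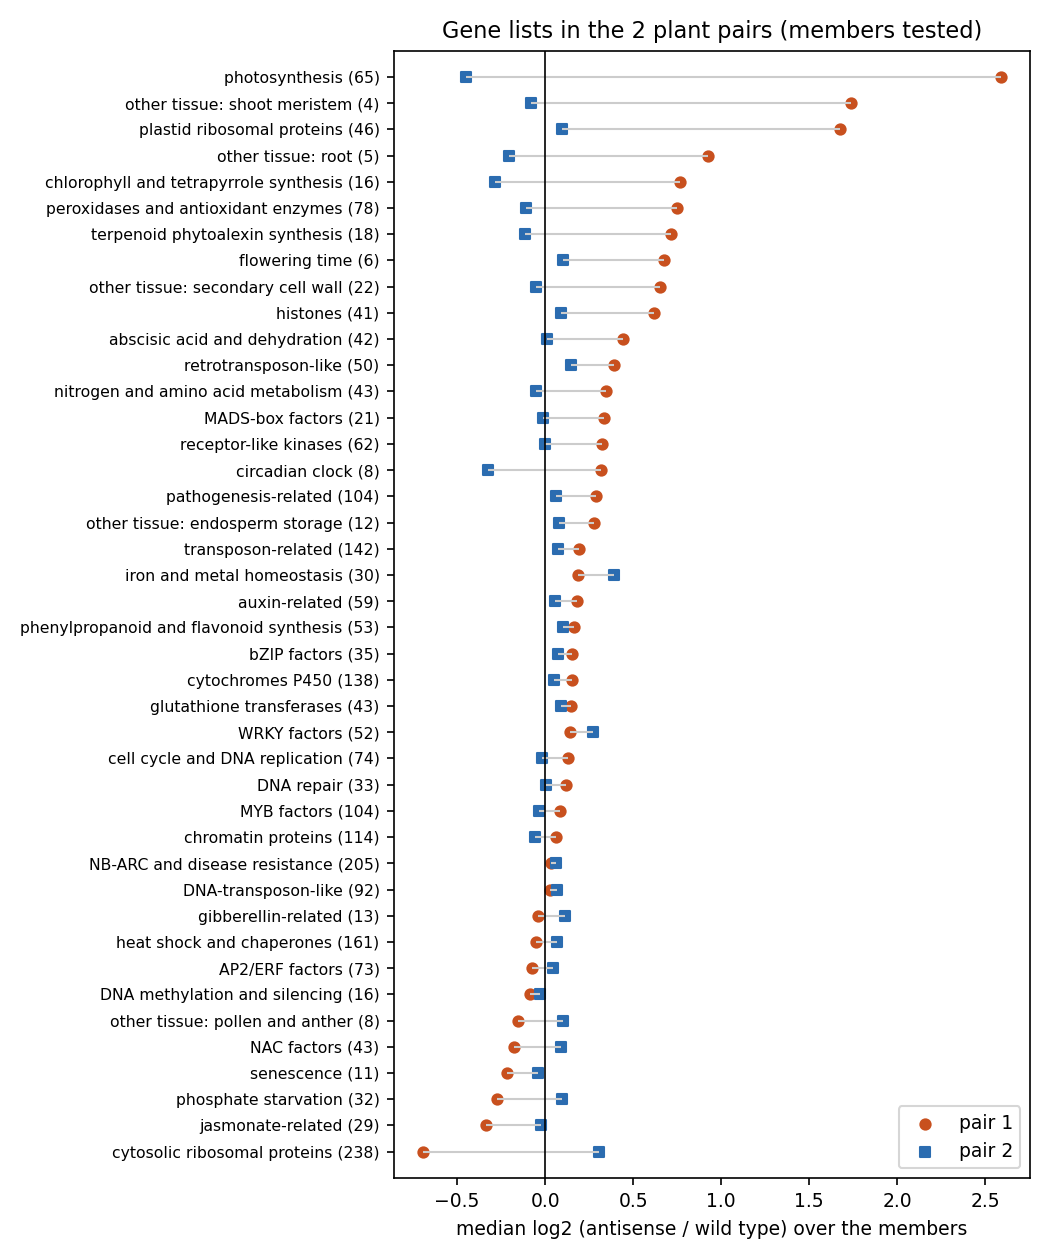
Each line is 1 gene list with the number of members tested in brackets, and the points give the median log2 ratio of antisense over wild type in pair 1 and pair 2. The photosynthesis list has the widest gap, with 2.59 in pair 1 and -0.45 in pair 2.

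The plants of one genotype were compared with one another. Antisense plants 1 and 2 differed by at least 2-fold in 339 genes (1.67%), among them a prolyl endopeptidase gene (Os04g0561500) that was 113-fold higher in plant 2. The plant labelled wild type 1 and wild-type plant 2 differed in 5199 genes (25.5%). Rubisco small subunit genes Os12g0291400 and Os12g0274700 were 150-fold and 125-fold lower in the plant labelled wild type 1, and a metallothionein (Os05g0202800) and a NAC gene described as GRAB2 (Os07g0684800) were 151-fold and 48.0-fold higher there. These genes were chosen after their values were seen. Wild-type plant 2 differed from antisense plants 1 and 2 in 804 and 907 genes, and the plant labelled wild type 1 in 4889 and 4676. Each comparison is 1 plant against 1 plant and has no replicate check. Across genes, the dye-swapped arrays correlated at r = 0.969 in pair 1 and 0.909 in pair 2 (rank correlations 0.957 and 0.769). The pairs correlated with one another at r = -0.02 (rank correlation -0.186), and genes are not independent replicates.

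Genes that differed in both pairs lay near one another more often than reordered genes. Among the 354 genes, 77 neighbouring pairs within 5 tested loci had the same direction, against a mean of 20.9 and at most 39 in 10000 permutations (permutation p = 1e-04, the smallest they can give). For higher genes there were 53 pairs against a mean of 19.7. For lower genes there were 24 against 1.19, most of them within 1 run of loci on chromosome 11. On chromosome 11, 7 of 8 tested loci from Os11g0224900 to Os11g0226800 were lower in both pairs, while the kinase gene Os11g0226000 had 0.71 and 0.08. Of the 4 disease resistance genes among them, Os11g0224900, Os11g0226700 and Os11g0226800 were at least 3.46-fold, 3.70-fold and 5.14-fold lower, with no antisense signal well above background, and Os11g0225300 had such a signal on 1 of 4 arrays. The integrase gene Os11g0224300, higher in both pairs, is the next tested locus. On chromosome 7, 5 of 6 tested loci around the En/Spm-like gene Os07g0431000 were higher, with log2 ratios of 6.50 and 5.81 for Os07g0429600, well above background in wild type on 2 of 4 arrays, and 7.26 and 5.33 for Os07g0429700. Chromosome 11 held 13 of the lower genes among 1111 tested loci (Fisher's exact test, adjusted p = 0.0023), but 7 of the 13 are those of the run above. Chromosome 3 held 1 among 2646 (adjusted p = 0.013), and chromosome 4 held 39 of the higher genes among 1776 (adjusted p = 0.045). The 39 include several runs of 3 higher genes near one another, so they are not independent units for Fisher's exact test.

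**Figure D4:**
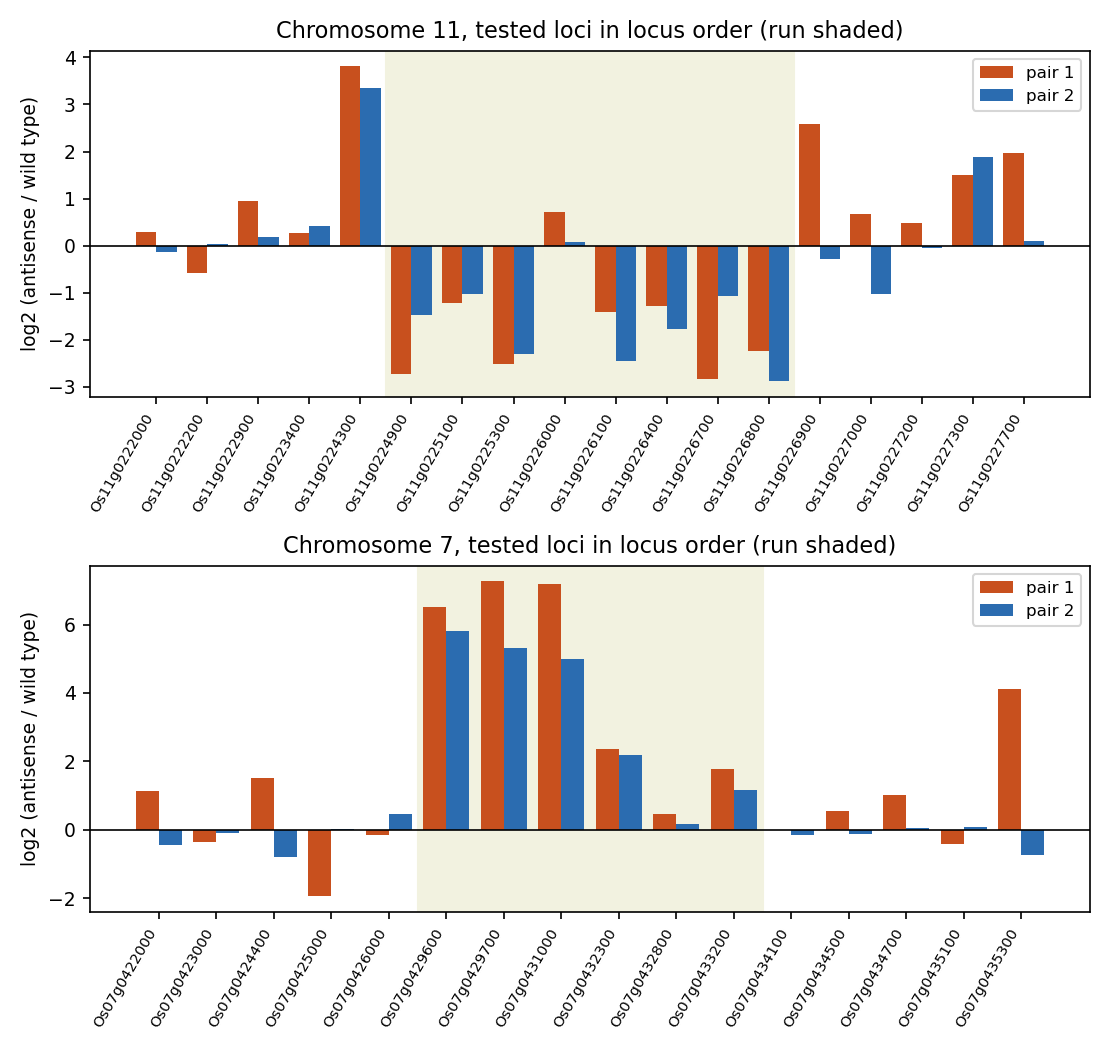
Bars give the log2 ratio of antisense over wild type in pair 1 and pair 2 for tested loci in locus order, with the run shaded and 5 tested loci on either side. On chromosome 11, 7 of 8 loci in the run are below -1 in both pairs, and on chromosome 7, 5 of 6 are above 1, with signals not well above background drawn as measured.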

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

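The tests of a mislabelled plant, another tissue, chance overlap and loss of a segment were chosen, or their bounds rewritten, only after the result was seen.

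Of the 19 probes named by area and kept out of the gene tests, the 2 of 1 area were at least 2-fold above wild type in pair 2. Array probes placed in the area of Os02g0306400 and described as OsNAAT1, nicotianamine aminotransferase of phytosiderophore synthesis, were 19.0-fold and 17.0-fold higher in antisense plant 2 than in wild-type plant 2. In pair 1 the same probes were 1.97-fold and 1.93-fold lower in the antisense plant, and the difference between pairs was not tested. Of the other 17, 1 probe of Os11g0597400 was 7.44-fold lower in the antisense plant in pair 1, at a log2 ratio of -0.03 in pair 2. No outlier test was run, since the 4 arrays hold 2 independent ratios.

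The plant labelled wild type 1 stood apart from the other 3 plants, with 5199 genes at least 2-fold different from wild-type plant 2. Degraded RNA would lower 5' probes more than 3' probes, but over 389 genes with both, the 5' minus 3' difference of its log2 ratio to wild-type plant 2 had a median of 0.0670 (95% bootstrap interval 0.03 to 0.10). Its OsDDM1b level of 8.28, like that of the antisense plants, goes with an antisense plant labelled as wild type, but the 47 genes at least 8-fold higher in pair 2 had a median of -0.0157 there against wild-type plant 2, where antisense plant 1 had 3.75, which argues against a sibling of this line. RNA of another listed tissue would raise its markers, but without the filter on dim probes the highest share of a list at least 2-fold higher there than in wild-type plant 2 was 5.45% (3 of 55 endosperm genes, with granule-bound starch synthase Os07g0412100 26.6-fold higher), against 7.44% of all genes, for lists of 15 to 59 genes. A plant from outside the series, a tissue without a list and another state of that leaf stay open, and no biological explanation was tested, since the labels give no group for one.

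Chance overlap of genes variable in both pairs could give part of the 284 genes at least 2-fold higher in both pairs, and how large a part was not settled. Reordering the directions of pair 2 among the 580 genes at least 2-fold different in both gave a mean of 270 and a highest count of 287, and without probes that resemble another locus the 200 genes left stood at the mean of 200. The reordering keeps the number of genes in each direction, so a rise shared by the pairs is partly counted as chance. At 4-fold the counts of 77 and, without probes that resemble another locus, 62 lay above the highest of 76 and 61. At 8-fold 31 genes were higher in both pairs, 1 was lower and 3 had opposite directions. At 16-fold 17 were higher in both and 1 had opposite directions. These totals all but fix the reordered counts (at most 32 and 17), so the reordering cannot decide at 8-fold and 16-fold. Probes that resemble a probe of another locus made up 29.6% of the genes, against 4.15% of all tested genes. Sequence shared with loci that have no probe on the array is not counted, so probes left after this filter need not be specific. The 29.6% lies between the bounds of 25% and 50% set against and for such probes, which leaves their share of the cause open. A change fixed in line 1-17 apart from the antisense construct, from tissue culture or from the insertion, cannot be told apart from an effect of the construct, because the design holds 1 line.

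Neighbouring genes differed in the same direction in 77 pairs. Tandem copies with similar probes could give such pairs, but 1.30% of them (1 pair) had probes that resemble each other. Tandem copies with unlike probes are not covered by this comparison, and the permutation did not keep neighbouring genes of a family together. Loss of the whole chromosome 11 segment from both copies would leave no signal in the antisense plants, yet 4 of its 8 tested loci were well above background there on all 4 arrays, and loss of 1 of 2 copies would lower each locus about 2-fold, yet Os11g0226000 had a log2 ratio of 0.40 ± 0.45 (SD, n = 2 pairs). The bound first written against such a loss, under 50% of these loci lower in both pairs, was not met, since 7 of 8 were lower (87.5%). Loss of a part of the segment, and a regional change of chromatin, stay open as untested hypotheses.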

How the results depend on the processing

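Of 617 values recomputed under other settings, 565 stayed within the limits set for an unchanged result, though several settings leave a ratio as it is by construction. In the 8 settings that move ratios, 12 of 188 named genes took the other direction, and 26 had it in 1 of the 2 pairs. The causes of the differences below were not tested, except where fewer genes or plants entered by construction. Alternatives said to be added were chosen after the data were seen. The planned fit of 4 arrays with a dye term and a replicate block could not be fitted. Added without the dye term (replicate correlation 0.903), the replicate block called 0 genes, as did no pairing, and changed no call. Aquantile moves no ratio within an array and tests nothing here, and a design of this size cannot show stability of a count of 0.

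Genes at least 2-fold higher in both pairs numbered 510 with the scanner software's processed signals and 510 with the deposited series table, and 153 with signal above background required in both channels, which removes genes dim in wild type. Lower genes numbered 165, 166 and, against wild-type plant 2 alone (added), 165, where 353 were higher. Against that plant alone both ratios share the same wild-type plant, so they are not independent and the counts are not like those of 2 pairs. With 1 pair left the counts ranged from 562 to 3379 higher and from 345 to 1510 lower, and neighbouring pairs from 234 to 3823. The lower end is always without pair 1. The scanner software's p gave 704 higher and 274 lower genes where limma called 0. Lists with a call numbered 3 with both channels required, 0 with an estimated correlation and 0 with fry. The transposon-related median was 0.0320 (adjusted p = 0.11) without the dim filter, 0.0592 (0.62) with both channels required, 0.10 (0.071) on the arrays with antisense in Cy3, 0.12 with an estimated correlation (0.90) and with fry (0.53), and 0.0763 (0.46) for DNA transposons alone. The cytosolic ribosomal list turned to 0.30 without pair 1 and was -0.69 without pair 2. The photosynthesis list passed the threshold with processed signals (1.07, adjusted p = 0.0083), the series table, median centring (0.80, 0.017), antisense in Cy5 alone (1.29, 0.0024) and the lists as first written (0.87, 0.039, added), and the histone list missed it with median centring (0.15, 0.054). At 1.5-fold the antisense plants differed in 1159 genes and the plant labelled wild type 1 from wild-type plant 2 in 9207, and with processed signals the antisense plants differed in 591. Median centring moved the median of all genes in pair 1 from 0.08 to -0.11. Between 69.6% and 74.1% of spots were above background, which limits what can be said of genes silent in wild type.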

Other observations

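The genes of this part were chosen after their values were seen, apart from Os04g0178300, Os04g0171800, Os04g0339000 and Os05g0198400. On chromosome 4, 3 of 5 tested loci in the cluster known for momilactone phytoalexin synthesis were at least 2-fold higher in both pairs. These 5 loci were counted from the first to the last of the higher genes, so that choice partly fixed the share. A copalyl diphosphate synthase (Os04g0178300) was at least 3.28-fold higher, a dehydrogenase (Os04g0179200) at least 3.69-fold and a cytochrome P450 described as CYP99A1 (Os04g0180400) at least 4.11-fold. All 3 were not well above background in wild type, so they entered the tested set through the antisense channel alone. The 18 tested genes of terpenoid phytoalexin synthesis had a median of 0.38 ± 0.59 (SD, n = 2 pairs), with 2 higher and 1 lower in both pairs (camera, adjusted p = 0.46). Other chromosome 4 genes higher in both pairs were a P450 described as CYP79A1 (Os04g0171800, 4.14-fold) and a P450 (Os04g0339000, 5.51-fold), the second well above background in wild type on 2 of 4 arrays. The cold-response genes Os09g0522000, described as CBF-like, and Os09g0522200, described as DRE-binding protein 1A, were lower, with log2 ratios of -3.28 and -1.89 for the first and -2.66 and -1.59 for the second in pairs 1 and 2. Wound-induced inhibitor genes Os01g0132000 and Os01g0124200 were lower too, with -4.58 and -1.44, and -1.20 and -4.03.

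Single metal genes had unlike values in the antisense siblings or in pair 2, while of the 30 genes of the iron and metal list 9 were at least 2-fold higher and 2 lower in pair 2, and 3 were higher in antisense plant 1 and 8 in plant 2 (camera over both pairs, adjusted p = 0.45). A zinc transporter gene (Os08g0207500) was 9.52-fold higher in pair 2, with a log2 ratio of -0.17 in pair 1, and 8.30-fold higher in antisense plant 2 than in plant 1. Zinc transporter genes Os05g0198400 and Os05g0472700 were 4.36-fold and 3.46-fold higher in pair 2. An Nramp gene (Os07g0258400) was 8.15-fold higher in antisense plant 1 than in plant 2. Endochitinase genes Os04g0494100 and Os04g0493400 had log2 ratios of -3.33 and -3.09 in pair 2 and of -0.07 and -0.28 in pair 1. Each of these is a value of 1 plant pair with no test.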
